A study of Homo sapiens with 8 samples.

How the data were processed

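The data were 8 two-colour arrays of total RNA from K562 cells with RIZ1 and K562 cells without it. The labels gave each array a replicate number from 1 to 4 and the cell in each channel. Nothing in the sources used here says whether the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.

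The values used were the deposited log ratios of 43196 array rows, taken as log2 ratios. Their base is not given in the sources used here, and log2 was taken as usual for such arrays. Image analysis, background correction and normalization are not given in the sources used here. The deposited medians per array lay between -0.005 and 0.025, near 0 before any centring here. No spot intensities were used here, so no filter on dim spots and no background correction could be tried, and depth has no meaning beyond the number of arrays. Of the rows, 246 held no value, and the missing rows per array ran from 598 to 3929. The SD of the log ratios per array ran from 0.365 to 1.16. Probe annotation gave 1 symbol to 23530 rows, several to 1576 and none to 18090, and 23458 of the first were matched by gene identifier to a RefSeq gene table, used for names only, with none of its coordinates. Genes of rows with several symbols are not named.

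Rows with identical values on all arrays were merged where they had the same clone accession or where neither had one in the annotation. This gave 39911 features, 1495 of them from several rows, 752 with an accession and 743 without. Each array was centred on its median. For each replicate number, the array with K562 + RIZ1 in channel 2 was subtracted from the array with it in channel 1 and divided by 2, which removes the dye effect and leaves 4 values. The dye component was the corresponding mean of both. A feature needed both arrays of at least 3 replicate numbers. R 4.3.3 and limma 3.58.1 fitted an intercept with empirical Bayes moderation, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Genes were the means of their features. The features of a gene were averaged even where they disagreed. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

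The design, the alternatives, the rule for named genes and 25 gene lists with 670 genes, of which 522 were measured, were chosen before the data were examined. The rule named *PRDM2*, *IGF1*, *IGF2*, *IGF1R*, *IRS1* and *IRS2* where measured. It then named the 12 largest genes each way past the threshold, or, where fewer than 5 passed, the 8 genes of smallest unadjusted p each way with 1 sign in every measured replicate, and up to 4 members of smallest p per list. *IGF2* had no tested feature of a single gene and is not analysed here. Lists of at least 5 genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and with fry. The lists covered insulin-like growth factor and PI3K signalling, erythroid, megakaryocyte, myeloid, lymphoid and fibroblast markers, cell cycle, p53, apoptosis, BCR-ABL targets, immediate early and interferon genes, chromatin, histones, ribosome, proteasome, heat shock, stress, cholesterol, glycolysis, oxidative phosphorylation and cytoskeleton. The mixed test of fry and array weights were added after the data were seen.

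The alternatives were no centring, scaled spread, quantile normalization, 8 arrays as separate values with and without a replicate block, each replicate left out, stricter and looser completeness, robust moderation, a 1.5-fold minimum, gene means, an unmoderated test, 1 feature per gene, each orientation alone, and no sign turned. The steps were tested on simulated data with the real spread of 38982 features and 200 changed ones. None of the simulated changes of 1 (log2) passed, 68.5% of those of 1.5 and 82.5% of those of 2 did, with 4 and 5 false calls for the latter sizes.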

Results

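Gene expression was compared between K562 cells carrying RIZ1 and K562 cells without it. K562 is an established human line from a chronic myeloid leukaemia in blast crisis. RIZ1 is a product of *PRDM2*, a histone H3 lysine 9 methyltransferase described as a tumour suppressor. Total RNA of both cells was hybridised together on 8 spotted two-colour arrays, which formed 4 replicate numbers of 2 arrays each. In every number, K562 + RIZ1 stood in channel 1 on 1 array and in channel 2 on the other. After spots with identical values were merged, 38982 features were tested, of which 21610 carried the symbol of 1 gene, and these made 12792 genes. The precision was limited by the number of arrays. The series title concerns the link between loss of RIZ1 and insulin-like growth factor 1 signalling, and the comparison asked which transcripts differed when RIZ1 was present.

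All log2 ratios below are coded as K562 + RIZ1 over K562, on the reading that channel 1 is the numerator of the deposited ratio. The sources used here do not state the numerator. The direction is therefore not settled: if channel 2 is the numerator, every sign below turns together. Counts of positive and negative values, here and for the gene lists, then exchange places, while the sizes, the counts past a threshold and which genes have opposite signs stay as they are.

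*PRDM2*, the gene introduced, had a log2 ratio of 0.50 ± 0.73 (SD, n = 4 replicate numbers), positive in 2 of 4 replicates, and 0.29 to 0.74 with 1 replicate left out. Its features did not behave alike. One gave 0.27 ± 0.21 (n = 4) and the other 0.74 ± 1.49 (n = 4), the latter carrying a single deposited value of -4.11 on the array of replicate 3 with K562 + RIZ1 in channel 2. In an exact two-sided sign-flip permutation test over the 4 replicate values, p was 0.5, and 0.13 is the smallest p this design allows. The limma test gave an adjusted p of 0.854. Whether the features lie within the introduced part of the gene is not given in the sources used here, so they do not settle whether the transgene was expressed.

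The insulin-like growth factor axis held a negative *IGF1* ratio and a positive *IGFBP2* ratio, as coded. *IGF1*, a growth factor that signals through the IGF1 receptor, had a log2 ratio of -0.65 ± 0.22 (n = 4), negative in 4 of 4 replicates. *IGFBP2*, a secreted protein that binds insulin-like growth factors, had 0.60 ± 0.22 (n = 4), positive in 4 of 4 replicates. Both passed limma's test when adjusted over the list alone (adjusted p = 0.0226 each), and neither passed over all genes (adjusted p = 0.854). The adjustment over a list alone was made within each gene list separately, with no correction across the lists. The series title also names insulin-like growth factor 1 signalling, so the choice of this list may not be independent of these data. The passes over the list alone therefore do not establish a change of either gene. The 4 *IGF1* features gave -0.52, -0.52, -1.24 and -0.12. The insulin receptor gene *INSR* had 0.33 ± 0.18 and *IGFBP4* had 0.31 ± 0.20, without passing. The receptor gene *IGF1R* had -0.13 ± 0.08, the adaptor genes *IRS1* and *IRS2* had 0.25 ± 0.37 and -0.22 ± 0.13, and none of the 3 passed (n = 4 each). Without replicate 4, *IRS1* had 0.076. The 4 *IRS2* features ranged from -0.040 to -0.66. The exact sign-flip permutation p was 0.13 for *IGF1*, *IGF1R* and *IRS2*, the smallest possible, and 0.25 for *IRS1*.

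**Figure D1:**
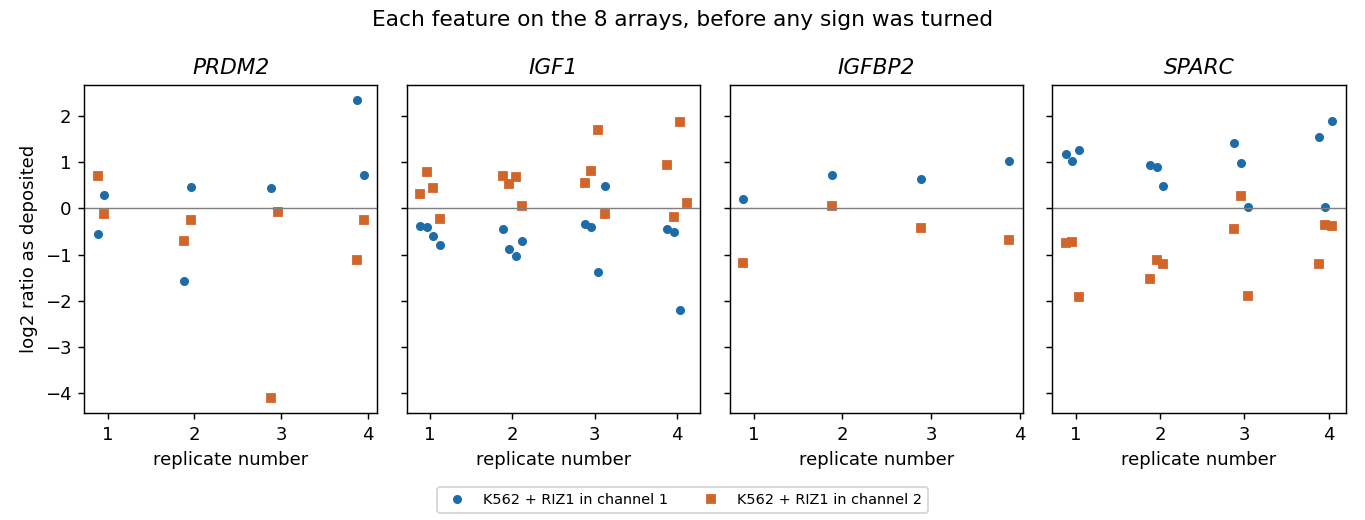
Log2 ratio as deposited (vertical axis) of each feature of *PRDM2*, *IGF1*, *IGFBP2* and *SPARC* on each array, against the replicate number (horizontal axis). Circles are arrays with K562 + RIZ1 in channel 1 and squares those with it in channel 2, and 1 *PRDM2* square lies at -4.11.

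Among all genes, *SPARC* had the smallest unadjusted p. It encodes a secreted matrix glycoprotein and had a log2 ratio of 0.96 ± 0.17 (n = 4), positive in 4 of 4 replicates, and its 3 features gave 1.12, 1.14 and 0.61. The other 7 positive genes of smallest p were *GRIN2D*, a glutamate receptor subunit gene (1.59 ± 0.39, n = 3), *FAM230C* (0.70 ± 0.18), the zinc transporter gene *SLC39A7* (0.87 ± 0.08, n = 3), *DERL2* of endoplasmic reticulum degradation (0.71 ± 0.22), *MAGEB2* (0.58 ± 0.10), *FGF13* (0.77 ± 0.27) and *FGFBP1* (0.71 ± 0.23). On the negative side stood *LOH12CR2* (-0.67 ± 0.20), *DGCR2* (-1.07 ± 0.37, n = 3), *IGF1*, *CPVL* (-0.67 ± 0.25), *CRB1* (-0.65 ± 0.25), *RCBTB2* (-0.71 ± 0.15, n = 3), *SLC35D3* (-0.63 ± 0.25) and *REST*, a transcriptional repressor of neuronal genes (-0.46 ± 0.06). Values without an n rest on 4 replicates. None of these 16 genes passed the adjusted threshold over all genes. The 2 features of *SLC35D3* gave -0.19 and -1.07. After turning, *SLC39A7* had a mean of 1.79 (standard error 1.03) on arrays with K562 + RIZ1 in channel 1. On those with it in channel 2 the mean was -0.02 (standard error 0.73). Each SD above is of replicate values that average 2 arrays, and single arrays could scatter more. Picking genes for small p also favours small SDs, so these SDs may understate the scatter. *FAM230C* had a mean of 1.16 on channel 1 arrays and 0.25 on channel 2 arrays. Standard errors of the orientations were also wide for *DGCR2* (0.75 and 0.51), *RCBTB2* (0.93 and 0.60), *DERL2* (0.47 and 0.56) and *REST* (0.36 and 0.37). For *GRIN2D* (0.15 and 0.70) and *CRB1* (0.47 and 0.22) they were wide in 1 orientation. They were smaller for *SPARC* (0.11 and 0.16) and *MAGEB2* (0.08 and 0.05).

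**Figure D2:**
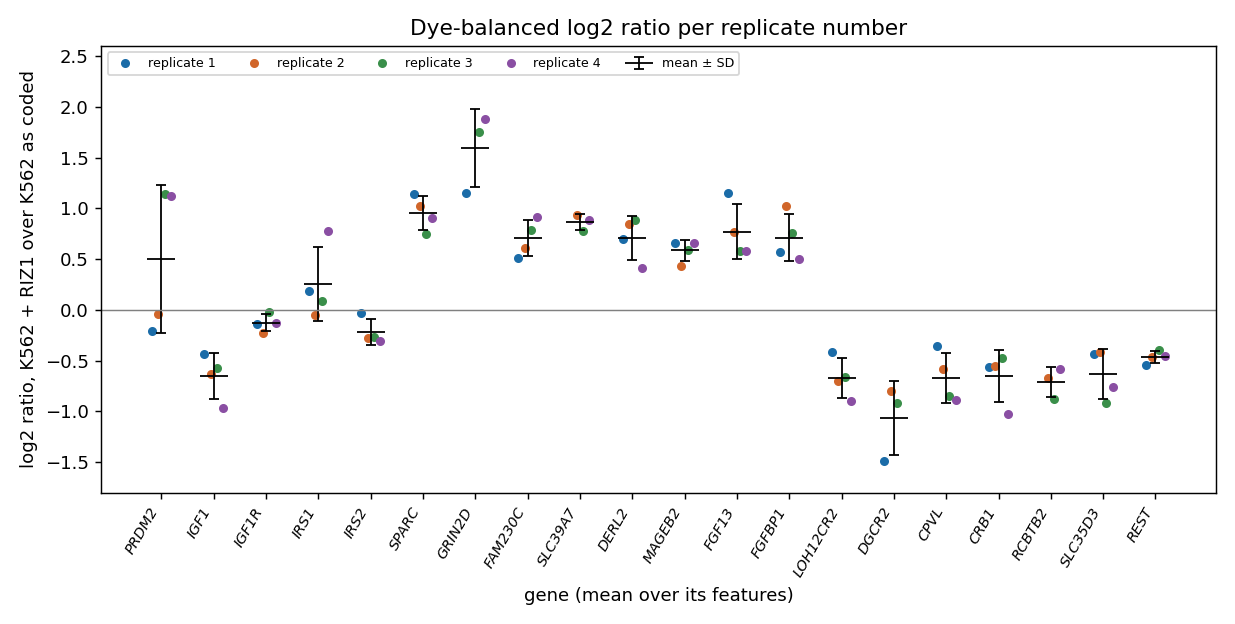
Dye-balanced log2 ratio (vertical axis) of the genes named by rule (horizontal axis), K562 + RIZ1 over K562 as coded. Points are replicate numbers, bars the mean ± SD, and *SPARC* lies at 0.96 ± 0.17 while *PRDM2* spreads over 0.50 ± 0.73.

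By limma, 0 of 38982 features had an adjusted p under 0.05, and the lowest adjusted p was 0.856. At an unadjusted p under 0.05 there were 1896 features, below the share of 0.05 that uniform p-values would give. Of these features, 1234 were positive and 662 negative as coded. At an unadjusted p under 0.01 there were 294, where 389.8 would be met by chance, and 176 without replicate 1. An ordinary one-sample test after adjustment also passed 0 features. Of the 12792 genes, 0 passed and 680 had an unadjusted p under 0.05, 495 positive and 185 negative. These 680 lay slightly above the share of 0.05. At an unadjusted p under 0.01 there were 112 genes, where 127.9 would be met by chance. Correlations of the dye-balanced log ratios across features between pairs of replicates ran from -0.01 to 0.095, and features are not independent replicates.

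The dye component, channel 1 over channel 2 irrespective of RNA, was shared more between replicates, with correlations across features of 0.116 to 0.221. For it, limma passed 0 features, with a lowest adjusted p of 0.329. An unadjusted p under 0.05 was found for 4207 features, above the share of 0.05 that uniform p-values would give. Under 0.01 there were 887, where 389.8 would be met by chance.

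Of 25 gene lists, 0 stood apart from the other genes by camera at an adjusted p under 0.05. The directional test of fry, which sets a list against 0, passed no list either, with a lowest adjusted p of 0.228. The mixed test of fry, which asks whether members change in either direction and was added after the data were seen, passed 4 lists, each with an adjusted p of 0.0137. These were the insulin-like growth factor list, the megakaryocyte markers, the fibroblast and matrix markers, and the histone genes. Their unadjusted p by the mixed test were 0.0022, 0.0016, 0.0013 and 0.0019, in that order. Of 10000 random lists of the same size, 0.42%, 0.65%, 0.59% and 0.69% had a mixed p as small. The mixed test's p ran smaller than these shares, so its adjusted p may be too small. Without *SPARC*, *IGF1* and *IGFBP2* the mixed test passed 1 list, the histone genes (adjusted p = 0.0465). Without replicate 4 the histone list did not pass the mixed test (adjusted p = 0.316). The insulin-like growth factor, megakaryocyte and fibroblast lists passed there (adjusted p = 0.0281 each). The cell cycle inhibitor and proteasome lists, which did not pass with all replicates, also passed there (adjusted p = 0.0281 each). Without replicate 3 the insulin-like growth factor list did not pass the mixed test (adjusted p = 0.547). The megakaryocyte (0.0490), fibroblast (0.0347) and histone lists (0.0490) passed it there. The mixed test passed 0 lists without replicate 1 and 0 without replicate 2.

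In the insulin-like growth factor list, 14 of 25 measured members were positive and 11 negative, and 2 passed when adjusted over the list alone. Passes over a list alone, here and for the lists below, are not corrected across the lists. The camera adjusted p of the insulin-like growth factor list was 0.947. Of 17 megakaryocyte markers, 8 were positive and 9 negative, and 2 passed over the list alone, *SPARC* and the transcription factor gene *FLI1* (0.50 ± 0.19, n = 4). The 2 *FLI1* features disagreed, at 1.08 and -0.09. The platelet chemokine gene *PF4* had -0.36 ± 0.29 without passing. The list's median was -0.04 and its mean 0.04, with camera's direction upward as coded (adjusted p = 0.947). Of 19 fibroblast and matrix markers, 15 were positive and 1 passed over the list alone, again *SPARC*, which both lists hold. *PDGFRB* had 0.37 ± 0.31, or 0.23 without replicate 4, and did not pass, and camera gave an adjusted p of 0.129. Of 17 histone genes, 12 were positive and 0 passed over the list alone. *H1-2* had 0.42 ± 0.17 and *H2AZ1* had 0.29 ± 0.12 (n = 4 each), and camera gave an adjusted p of 0.301.

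The mitosis list lay closest to camera's threshold, followed by the cytoskeleton and adhesion list. Of 25 mitosis genes, 19 were positive, among them the cyclin gene *CCNB2* (0.30 ± 0.13) and the kinesin gene *KIF23* (0.33 ± 0.18), and 0 passed over the list alone (camera adjusted p = 0.0588; adjusted p = 0.589 with an estimated correlation). Of 22 S-phase genes, 16 were positive (camera adjusted p = 0.0762), with *FEN1* at 0.39 ± 0.24 and *PCNA* at 0.36 ± 0.24. Of 20 cytoskeleton and adhesion genes, 17 were positive (camera adjusted p = 0.060). Among them were *ITGB1* at 0.28 ± 0.18 and *PFN1* at 0.27 ± 0.20. Of 22 oxidative phosphorylation genes, 18 were positive (camera adjusted p = 0.0762), with *SDHD* at 0.28 ± 0.10. Between orientations the sign turned for *SDHD*, with -0.38 where K562 + RIZ1 was in channel 1 and 0.93 where it was in channel 2, and for *ITGB1*, with -0.24 and 0.80. None of these lists passed, and the estimated correlation gave each an adjusted p of 0.589. The mitosis list passed camera when the arrays' spread was scaled (adjusted p = 0.0050), after quantile normalization (0.00286) and without replicate 4 (0.0125). With an estimated correlation these became adjusted p = 0.563, 0.514 and 0.867. Without replicate 2, the lists that passed were S phase (adjusted p = 0.0493), erythroid regulators (0.0493) and cytoskeleton (0.0356), each with an adjusted p = 0.801 with an estimated correlation. On arrays with K562 + RIZ1 in channel 2 alone, mitosis (0.00428), erythroid regulators, glycolysis, oxidative phosphorylation and the proteasome (0.0449 each) passed. With an estimated correlation their adjusted p lay between 0.423 and 0.499. Arrays of 1 orientation alone keep the dye component, so these passes mix dye and comparison. With no sign turned, fry's direction was downward for each of these lists (adjusted p of 0.189 to 0.640). Turning channel 2 arrays makes that upward. In channel 1 arrays alone, fry's direction was downward for glycolysis and the proteasome and upward for the others (adjusted p = 0.924 each).

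Erythroid genes, which K562 cells can express, did not pass as a list. Of 21 erythroid regulators and membrane proteins, 15 were positive, with *LMO2* at 0.41 ± 0.14 and *RHAG* at 0.36 ± 0.26 (camera adjusted p = 0.0957; adjusted p = 0.589 with an estimated correlation). Of 20 globin and haem genes, 13 were positive (camera adjusted p = 0.212). The fetal globin gene *HBG1* had 0.39 ± 0.28 and *HBA2* had -0.36 ± 0.27. Of 18 myeloid markers, 13 were positive (camera adjusted p = 0.963), and *S100A8* had -0.47 ± 0.33. Of 18 lymphoid markers, 11 were positive (camera adjusted p = 0.457), and *CD3D* had 0.44 ± 0.19. The sign turned between channel 1 and channel 2 arrays for *HBA2* (-0.76 and 0.043) and *CD3D* (-0.081 and 0.95).

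Signalling lists gave no call either. Of 25 PI3K, AKT and mTOR genes, 19 were positive (camera adjusted p = 0.279). *TSC1* had 0.77 ± 0.42 and *EIF4EBP1* had -0.47 ± 0.31. The 2 features of *EIF4EBP1* gave -0.82 and -0.11. *TSC1* had 0.06 on arrays with K562 + RIZ1 in channel 1 and 1.47 on the others. Of 26 targets of BCR-ABL and JAK-STAT signalling, 21 were positive (camera adjusted p = 0.207), with *ID1* at 0.30 ± 0.18. Of 22 immediate early genes, 11 were positive (camera adjusted p = 0.613), with *KLF2* at 0.47 ± 0.19 and *EGR1* at 0.76 ± 0.56. The 2 features of *KLF2* gave 0.15 and 0.84. Of 17 cell cycle inhibitors and p53 targets, 10 were positive (camera adjusted p = 0.947). The inhibitor gene *CDKN1C* had -0.54 ± 0.24 and *BTG1* had 0.40 ± 0.16. Of 24 apoptosis genes, 14 were positive (camera adjusted p = 0.324). Of 20 interferon response genes, 10 were positive, with *IFITM3* at -0.32 ± 0.19, and the median of 0.03 and mean of 0.06 stood against a downward camera direction as coded (adjusted p = 0.947). *IFITM3* had -0.83 on channel 1 arrays and 0.20 on channel 2 arrays.

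Chromatin and housekeeping lists completed the set. Of 24 histone methylation and PRDM genes, 13 were positive (camera adjusted p = 0.856), with the demethylase gene *KDM1A* at 0.40 ± 0.10. The 3 features of *KDM1A* gave 0.077, 0.49 and 0.64. Positive members numbered 10 of 19 ribosomal protein genes (adjusted p = 0.947), 16 of 24 proteasome genes (0.303), 11 of 18 heat shock genes (0.677), 10 of 18 cholesterol synthesis genes (0.712), 18 of 23 glycolysis and hypoxia genes (0.457), and 12 of 20 amino acid and endoplasmic reticulum stress genes (0.947), each with its camera adjusted p. Among their members, *RPS12* had 0.44 ± 0.28, *HSPH1* 0.42 ± 0.23 and *PDIA4* -0.36 ± 0.12 (n = 4 each), and none passed over its list alone.

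**Figure D3:**
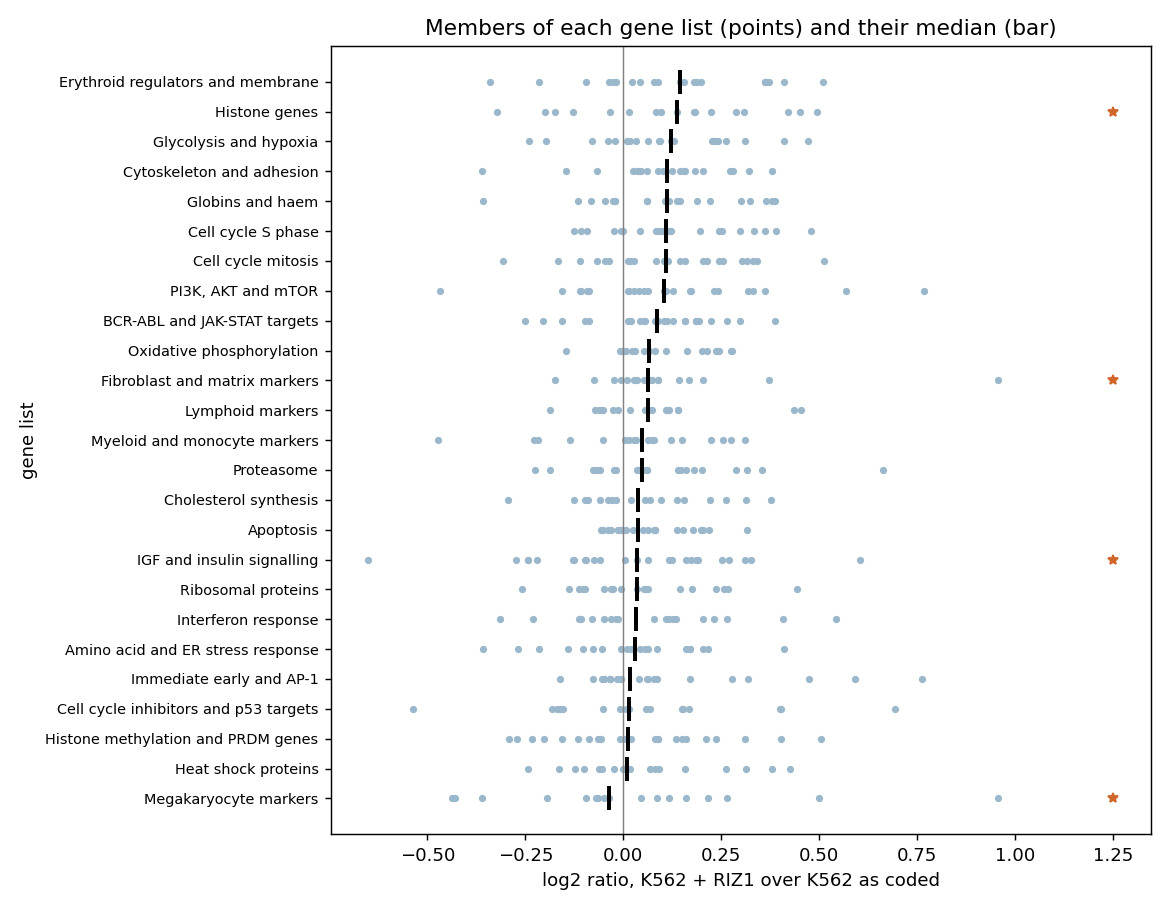
Log2 ratio of the measured members of each of 25 gene lists (points, horizontal axis, K562 + RIZ1 over K562 as coded) with the list median (black bar), lists on the vertical axis. Stars mark the 4 lists that passed the mixed test, and medians run from -0.04 for the megakaryocyte markers to 0.14 for the erythroid regulators.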

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

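All tests of explanations reported here were chosen after the result was seen, except the simulated power. The groups of 4 examined for a sample far from the others numbered 112, of which 9 were picked out where chance gives about 5.6.

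The array of replicate 4 with K562 + RIZ1 in channel 1 held 3929 missing rows, far from the next of 1134 in its orientation. Single replicate values lay far from the other 3 for *IRS2* (-0.034, nearest -0.26), *CRB1* (-1.03, nearest -0.56), *FEN1* (0.74, nearest 0.29), *RPS14* (-0.54, nearest -0.20), *MSMO1* (0.77, nearest 0.20), *PSMD12* (-0.16, nearest 0.87), *PSMA1* (0.11, nearest 0.37) and *UAP1* (0.15, nearest 0.47).

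No feature passed the adjusted threshold, and whether the wide array of replicate 4 hides calls stays open. The lower of the lowest adjusted p without replicate 4 and with array weights was 0.804, which decides nothing at this power. Features at an unadjusted p under 0.01 numbered 405 and 445 in these settings against 294 with all replicates weighted equally, but 176, 243 and 203 without replicates 1, 2 and 3, and 449 with scaled spread, which keeps replicate 4. Simulated changes of 1 (log2) on this spread were called in 0% of cases. Too little power with 4 replicates of this spread may therefore account for the missing calls up to that size. Changes of 1.5 were called in 68.5% of cases, with 200 features changed by the same size at once. Fewer changed features were not simulated, so this share need not hold for them. Small differences between the cells stay open and untested.

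The log ratios of *IGF1*, *IGFBP2* and *SPARC* kept their sign by more than 1 standard error in both dye orientations for 3 of 3 genes. A constant dye effect already cancels in the dye-balanced ratio. *IGFBP2* and *SPARC* were also picked for small p on these same arrays. The agreement of orientations therefore decides nothing more about a dye bias in these genes. Cross-hybridisation of these clones was not tested. A difference between the cells may be a hypothesis for them, found and tested on the same data.

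By camera, 24 of 25 lists lay above the other genes, as coded. A bias between bright and dim spots stays open: medians of housekeeping lists and of lists of genes silent in K562 differed by -0.00484, but brightness was assumed from the lists and not measured. With 8 sign patterns of the replicate values the splits are too few for a share under 0.05. The real pattern gave 24 lists on 1 side, the highest other 23, and 1 of the 8 patterns was as high.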

How the results depend on the processing

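Array weights, the mixed list test and the setting without *SPARC*, *IGF1* and *IGFBP2* were chosen after the data were seen, and the other settings before. The count of changed features and the count of features with a dye effect were 0 under each alternative run, including without each replicate in turn and with the replicate block. Camera's count of shifted lists, 0 in the main setting, was 1 with scaled spread, 1 with quantile normalization, 1 with 1 feature per gene, 3 with array weights, 5 on arrays with K562 + RIZ1 in channel 2 alone, and 0 to 3 with a replicate left out (3 without replicate 2 and 1 without replicate 4). Where an estimated correlation was run, camera gave these lists adjusted p of 0.423 to 0.867. It was not run with 1 feature per gene or array weights. The 8 arrays fitted with the replicate block gave 1 list and 0 features, and without the block 1 list and 0 features. An estimated correlation was not run for these fits of 8 arrays. Same-number arrays deviated with correlations of 0.00995, -0.00838, -0.00221 and 0.0181, so no shared variation of same-number arrays was detectable, and 1 of 8 arrays deviated most like the array of its own number. This does not show that they hold different RNA. The block changed no call of a feature. The count of lists with members changed in either direction, 4 in the main setting, was 10 with scaled spread, 9 with quantile normalization, 1 with no sign turned, 0 in channel 1 arrays alone, 18 in channel 2 arrays alone, 0 with 1 feature per gene, 1 without *SPARC*, *IGF1* and *IGFBP2*, and 0 to 5 with a replicate left out. An orientation alone keeps the dye component, so its counts mix dye and comparison. The cause of the other differences was not tested. What signal over background limits could not be examined without intensities.

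*PRDM2* was 0.29 to 0.74 with a replicate left out. The alternatives were run on *PRDM2* and on 118 other named genes, including *UAP1* and *ETNK1*, which were chosen after their values were seen. Of 1877 pairs of 1 of these 118 genes and an alternative, 1789 kept their sign, 88 had the other sign, and none passed the adjusted threshold. *PRDM2* is listed below but not counted in these pairs. With no array's sign turned, a setting that by construction replaces the comparison by the dye component, the log2 ratios that changed sign were *PRDM2* -0.25, *IRS1* -0.017, *GRIN2D* -0.33, *DERL2* -0.21, *MAGEB2* -0.13, *FGF13* -0.19, *FGFBP1* -0.25, *LOH12CR2* 0.088, *CPVL* 0.25, *RCBTB2* 0.083, *SLC35D3* 0.15, *REST* 0.26, *TSC1* -0.71, *PIK3CG* -0.14, *FOXO3* -0.0029, *HBG1* -0.034, *HBZ* -0.23, *LMO2* -0.11, *RHAG* -0.21, *CTSG* -0.46, *CD3D* -0.52 and *CD79B* 0.26. Further ones were *CD3E* -0.0071, *PDGFRB* -0.14, *THY1* -0.20, *COL3A1* -0.089, *PCNA* -0.24, *CCNB2* -0.19, *CCNA2* -0.079, *BTG1* -0.086, *CDKN2A* -0.18, *CYCS* -0.23, *CASP1* -0.026, *FADD* -0.095, *SPRY2* -0.12, *KLF2* -0.32, *FOSB* -0.043, *MX1* -0.19, *ISG15* -0.22, *KDM1A* -0.14, *EED* -0.16, *EZH1* 0.11, *PRDM15* 0.41 and *H1-2* -0.14. The last of them were *H2AZ1* -0.16, *RPS14* 0.17, *RPL3* -0.19, *MSMO1* -0.24, *IDI1* -0.098, *HMGCS1* -0.23, *STARD4* -0.017, *PFKFB4* -0.15, *SLC2A3* -0.29, *DDIT3* -0.34, *ATF4* -0.20, *HSPA8* -0.10, *SDHD* -0.65, *NDUFB3* -0.092, *NDUFS1* -0.28, *PSMD12* -0.43, *PSMA1* -0.37, *PSMD2* -0.21, *ITGB1* -0.52, *PFN1* -0.11, *UAP1* -0.040 and *ETNK1* -0.19. On arrays with K562 + RIZ1 in channel 1 alone they were *CTSG* -0.18, *CD3D* -0.081, *CD79B* 0.072, *CYCS* -0.016, *PRDM15* 0.11, *SDHD* -0.38, *NDUFS1* -0.061, *PSMA1* -0.051, *PSMD2* -0.013, *ITGB1* -0.24 and *ETNK1* -0.058. In channel 2 alone they were *SLC39A7* -0.016, *HBA2* 0.043, *ALAS1* -0.089, *CSF3R* 0.19, *RRM1* -0.082, *BAK1* -0.090, *IFITM3* 0.20, *H1-1* -0.045, *PFKP* 0.19, *HSPB1* 0.068 and *ITGA5* -0.30. With both arrays of all 4 replicate numbers required, the sign of *NDUFV1* turned, to -0.069. A single orientation keeps the dye component, which the dye-balanced ratio removes, so its signs mix dye and comparison. For *NDUFV1* the completeness filter dropped a feature at 0.72 (n = 3) and kept the other at -0.069 (n = 4).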

Other observations

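Among the tests here, only the splits for camera were set before their result was seen. Several genes had more than 1 clone moving the same way in the fit of 8 arrays. At an unadjusted p under 0.05 and with 1 sign stood 3 of 3 features of *SPARC*, 3 of 4 of *IGF1*, 3 of 4 of *UAP1* and 3 of 7 of *ETNK1*, these *UAP1* features at 0.49, 0.57 and 0.57 and these *ETNK1* features at 0.40, 0.35 and 0.28. Pairs of features moved together for *KDM1A* (0.49 and 0.64, 2 of its 3 features), *LMO2* (0.30 and 0.52), *PCNA* (0.33 and 0.40), *KIF23* (0.36 and 0.30), *CA2* (0.28 and 0.45), *CDKN1C* (-0.32 and -0.76) and *PDIA4* (-0.24 and -0.48). *UAP1* and *ETNK1* were chosen after their values were seen. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many such genes, the real one with 46, and the highest other had 34, the smallest share that 35 splits can give. Several counts were put through these splits without correction, so this share does not exclude chance splitting. It also assumes that the 2 arrays of a replicate number are independent, which is not known. In each replicate, the array labelled number 1 had K562 + RIZ1 in channel 1. A difference by array number can therefore not be told apart from the comparison. With the 4 replicate values the real count was 40 and the highest other of 8 sign patterns 25, 1 of 8 being as large, and 8 patterns are too few for a share under 0.05.

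For the count of features at an unadjusted p under 0.01 in the fit of 8 arrays, 1 of 35 splits was as large, the real one with 322, the highest other having 279. Even the real count lay below the 389.8 that uniform p-values would give. For lists passing the mixed test in that fit, 1 of 35 splits was as large, the real one with 3, the highest other having 1. For both counts the share is again the smallest that 35 splits can give, uncorrected for the several counts tried. It rests on the same independence of the 8 arrays, so chance splitting is not excluded. In the fit of 4 replicate values, *SPARC* is in 2 of the lists that passed, and 1 list passed without *SPARC*, *IGF1* and *IGFBP2*. Whether these genes carry the count in the fit of 8 arrays was not tested. For features past the adjusted threshold, 35 of 35 splits gave 0, the real one included, which decides nothing. For lists past camera, 2 of 35 splits gave as many as the real 1, the highest other giving 3, so chance is not excluded. With the 4 replicate values, the real sign pattern gave 294 features at an unadjusted p under 0.01, the highest other of 8 gave 248, and 1 of 8 was as large. The mixed test there passed 4 lists with the real pattern and 0 with the highest other, 1 of 8 being as large. For both, 8 patterns are too few for a share under 0.05.

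A hypothesis that *SPARC* and *FLI1* are part of a shift of all megakaryocyte markers was tested on the other 15 measured members. Their median log2 ratio was -0.050 with an SD of 0.22, so these other members showed no upward shift as coded. That they lay below *SPARC* and *FLI1* decides nothing, since both genes were picked for small p from this same list. The *FLI1* mean also rests on 2 features that disagreed, at 1.08 and -0.09.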
